A study of Mus musculus with 2 samples.

How the data were processed

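H3K9me3 chromatin immunoprecipitation and sequencing data from the neural tube of B6NCrl mouse embryos at day 13.5 were used, from 2 biological replicates of 1 group. Per the labels, each replicate was tissue of males and females together, and both formed a single group with no treatment or second tissue. Of 4 deposited peak lists, 1 was called on each replicate alone and 1 on both replicates pooled, and the replicated list was made from the other 3, per the manifests deposited with the files. Each replicate had its own control file, and the pooled list used both, according to the same manifests. Peak calling with different controls can itself make the replicates differ. The assembly was mm10, per the labels; the aligner, the peak caller and their versions are not given in the sources used here. Each row of the replicated list was found to equal a row of the pooled list, so its values are those of pooled reads.

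For each peak, the deposited lists give a fold enrichment over control as a linear ratio, made by the authors. The authors also give a −log10 p and a −log10 q per peak, and no peak had a −log10 p under 2, which is taken as the limit of their calling. A display score per peak, scaled by the authors to whole numbers within a list, was used here only to rank peaks. Neither read counts nor library totals were used, so the depth is unknown and no interval that needs it is given. Many −log10 p values are tied, which limits the ranking of weak peaks.

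Peaks were compared with GRCm38.p6, whose chromosome lengths equal those of mm10, and with the GENCODE M21 annotation of the same build. Chromosomes 1 to 19 and X were used. Peaks on Y and on unplaced contigs were left out of the comparisons and are described in the closing section. The soft-masking of the genome sequence served as the repeat annotation, and its method is not given in the sources used here. Each observed overlap was set against 1000 rotations, or 10000 for the gene types and symbol families of the closing section. In a rotation, all peaks of a chromosome were shifted together by a random distance along its sequenced part, wrapping at the end. A rotation keeps peak widths, the spacing of peaks and the clustering of genes. The 2-sided rotation permutation p cannot go below 0.002 with 1000 rotations, or below 0.0002 with 10000. Adjustment was by Benjamini-Hochberg over the 4 features or the 24 gene lists. The position of coverage within zinc finger genes was tested by 100000 sign permutations over clusters of genes within 500 kb.

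An overlap of at least 1 bp counted, between a peak and the span of a gene from its first to its last annotated base. The gene lists, their tests and most alternatives were fixed before the data were examined; the beta protocadherins alone, the imprinted genes counted once, the defensin list without Def6 and Def8 and several tests of the closing section were chosen later. By the same rule, the genes named were the 10 protein-coding genes with the most covered bases, the 10 with the highest fold enrichment, and up to 3 members per list with the highest fold enrichment, each also overlapped in both replicates' own lists. The rule also named the 5 replicated peaks of highest fold enrichment and the 5 widest. Members named for being few were chosen after their values were seen. The defensin list, made by symbol, also took Def6 and Def8, which are not defensins, and Def8, the strongest of that list, was left out of the named genes. The lists overlap slightly. For example, Zfp42 is both a zinc finger and a pluripotency gene, Fkbp6 is on the imprinted and the germline list, and Rpl10l on the ribosomal protein and the germline list. In the replicate values, the percent in each replicate's own list was averaged over the 2 lists; these are longer than the replicated list, so their percentages are not comparable with it in level. With 2 replicates an SD measures little more than their difference.

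For the closing section, 31-mers were sampled every 5 bp in peaks and last exons and counted on both strands of chromosomes 1 to 19, X and Y. C2H2 finger motifs and KRAB boxes were searched in the longest open reading frame of protein-coding transcripts, and intervals were taken from 2000 bootstraps over gene clusters. Alternatives covered the peak threshold (−log10 q of at least 2), peak number, the overlap counted, merging within 1 kb, each replicate's list alone, promoter width, the rotation space, and Fisher's exact test or 10000 length-matched lists in place of rotation. The rotation tests were tested on simulated peak sets on 4 chromosomes with 5437 genes and 200 rotations. With nothing planted, 3 of 40 clustered and 1 of 40 scattered sets were called, and 3 of 40 for replicate overlap, at a p under 0.05. With an effect planted, 40 of 40 were called for gene lists and 40 of 40 for replicate overlap. These effects were large: mean shares were 62.2% in planted gene lists against 25.25% in scattered ones, and 61.2% against 3.11% for replicate overlap. Simulated peaks lay in small clumps, so false calls were not tried under clustering as dense as over the protocadherins. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.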

Results

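Trimethylation of lysine 9 of histone H3 (H3K9me3), a mark of silent heterochromatin, was mapped by chromatin immunoprecipitation and sequencing in the neural tube of B6NCrl mouse embryos at day 13.5. The neural tube is the embryonic tissue that gives rise to brain and spinal cord, and each of the 2 biological replicates held tissue of both sexes. The samples formed 1 group, so the comparisons were between the replicates and between the peaks and the genome that they lay in. Replicate 1 had 56849 peaks covering 17.0 Mb, with a median width of 236 bp, and replicate 2 had 68041 peaks covering 20.5 Mb, with a median width of 240 bp. A list called on both replicates together held 108091 peaks over 39.1 Mb, and the authors' replicated list kept 30566 of them, over 18.7 Mb, with a median width of 494 bp. The median fold enrichment over control, which is the authors' own value for each peak, was 3.57 in replicate 1, 3.16 in replicate 2 and 3.70 in the replicated list. Read counts were not used here, so the sequencing depth behind each peak is unknown. Coordinates are those of mm10, counted from 1.

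The first comparison asked how far the replicates shared their peaks. The clustered protocadherin genes, the zinc finger gene clusters and the vomeronasal receptor clusters carried peaks in both replicates. Most peaks of each replicate, however, were found in that replicate alone, the weak ones more often than the strong. Of the peaks of replicate 1 on chromosomes 1 to 19 and X, 42.4% (23958 of 56467) were overlapped by a peak of replicate 2. Of those of replicate 2, 35.1% (23778 of 67661) were overlapped by a peak of replicate 1. Rotating the peaks of the other replicate along each chromosome gave medians of 1.74% and 1.45%, and none of 1000 rotations reached the observed share in either direction (2-sided rotation permutation p = 0.002, the smallest that these rotations can give). Sharing rose with peak strength. In the 10% of peaks with the highest −log10 p, 77.0% of replicate 1 and 72.6% of replicate 2 were shared, against 27.9% and 20.9% in the lowest 10%. The rotations were not repeated by strength class, and peak width was not held equal between the classes. Where peaks overlapped, their fold enrichments ranked only loosely alike, with a Spearman correlation of 0.175 across 23958 peak pairs, which are not independent replicates. Both lists held many tied values: the 10 commonest −log10 p values covered 67.6% of the peaks of replicate 1 and 70.9% of those of replicate 2. When an overlap had to cover 50% of each peak, the shared percentages were 20.8% and 17.4%.

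**Figure D1:**
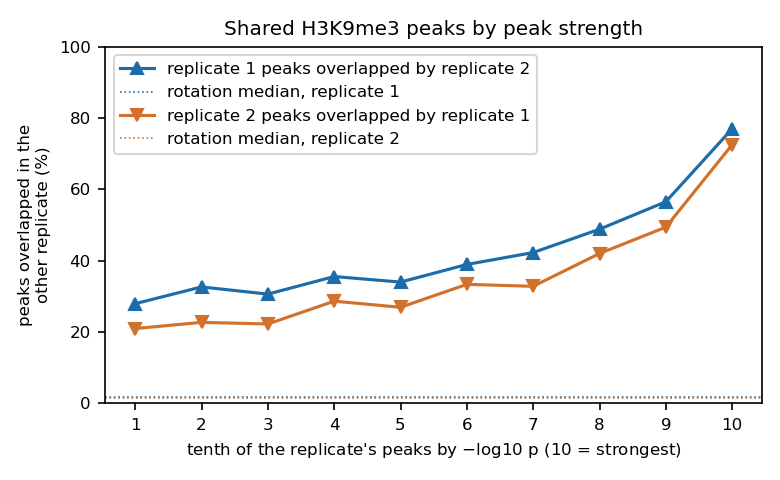
The vertical axis gives the percent of peaks of 1 replicate overlapped by a peak of the other, and the horizontal axis the 10 strength classes of its peaks by −log10 p, 10 being the strongest. The shared percent goes from 27.9% to 77.0% in replicate 1 (blue) and from 20.9% to 72.6% in replicate 2 (orange). The dotted rotation medians, at 1.74% and 1.45%, are those of all peaks of a replicate and not of each class.

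The replicated list kept 28.3% of the pooled peaks and 47.7% of their covered length. The kept peaks were the wider and stronger ones: their median width was 494 bp against 233 bp for the others, and their median fold enrichment 3.70 against 2.99 for all pooled peaks and 2.79 for those left out. Among the pooled peaks with the highest display scores, 95.3% of the top 10% were kept, and 0.805% of the lowest 10%. Every one of the 12238 pooled peaks of which both replicates covered at least 50% was kept. The other 18328 kept peaks did not meet that criterion, and 22106 of the kept peaks were overlapped by at least 1 bp in both replicates' own lists. All further comparisons used the replicated list, with each replicate's own list beside it.

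Peaks were unevenly spread over the chromosomes, with chromosome 7 far above the rest and X the lowest. Chromosome 7, which holds large clusters of zinc finger, vomeronasal receptor, Nlrp and pregnancy-specific glycoprotein genes, carried 16% of the covered length in 5.54% of the sequence. Its covered length per Mb was 2.88 times that of chromosomes 1 to 19 and X together in the replicated list, and 2.46 ± 0.02 times (SD, n = 2) in the replicates' own lists. Chromosome 17 followed at 1.96 times (replicates 1.81 ± 0.04), then chromosome 4 at 1.43 (1.33 ± 0.03) and chromosome 13 at 1.36 (1.29 ± 0.02). Chromosome X lay at 0.219 times (0.431 ± 0.043), and chromosomes 14, 15 and 1 at 0.547, 0.551 and 0.581 times. These are lengths of called peaks, not adjusted for the copy number of X in tissue of both sexes. The low value of X is therefore not a measure of how much H3K9me3 it carries. The distances of chromosomes 7, 17 and X from a ratio of 1 were much larger than the SD between replicates. Chromosomes 4 and 13 lay close to each other, as did 14 and 15. No test was run on these distances and gaps, and an SD of 2 replicates measures little more than their difference. The covered length was also concentrated within chromosomes: the 20 densest 1-Mb windows of 2645 held 17.7% of it, and the 100 densest 44.8%. The densest window, on chromosome 18 from 37000001 to 38000000, lay over the protocadherins, with 297 kb covered. The next, on chromosome 13 from 61000001 to 62000000, lay over the placental cathepsin genes Ctsj, Ctsq, Ctsr and Ctsm, with 217 kb covered.

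**Figure D2:**
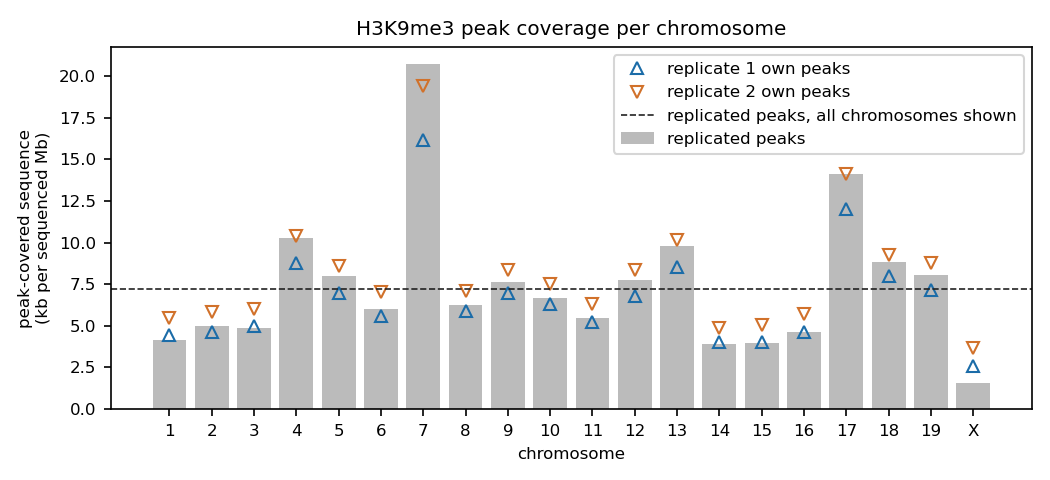
Bars give the sequence covered by replicated peaks in kb per sequenced Mb of each chromosome, triangles the same for each replicate's own peaks, and the dashed line the value over all chromosomes shown (7.18). Chromosome 7 stands highest in both replicates and in the replicated list, and X lowest.

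Within chromosomes, H3K9me3 peaks were enriched outside protein-coding genes and in the exons of those genes, and depleted in their introns. Only protein-coding genes were counted here, so genes of other types and pseudogenes fell under intergenic sequence. Intergenic sequence held 67.4% of the covered bases, against a rotation median of 57.9% (rotation permutation p = 0.002, adjusted p = 0.00266). Introns of protein-coding genes held 24.8%, against 36% (adjusted p = 0.00266), and exons 4.96%, against 3.35% (adjusted p = 0.00266, all from the same permutation test). Promoters, taken as 1 kb to each side of a transcription start, held 2.81%, against 2.77% (rotation permutation p = 0.877). The replicates' own lists gave 67.8% ± 0.28 for intergenic sequence, 25.4% ± 0.18 for introns, 4.38% ± 0.31 for exons and 2.46% ± 0.15 for promoters (SD, n = 2). Repeat-masked bases made up 34.5% of the covered length, which did not differ detectably from the rotation median of 33.8% (permutation p = 0.374). The peaks were richer in G and C than the rotated positions, at 44.1% against 42.1% (p = 0.002, the smallest that the permutation can give). Stretches of 31 bp found once in the assembled chromosomes made up 89.7% of the sampled stretches in replicated peaks, against 84% at rotated positions, and those present 100 times or more made up 1.18% against 7.36%. Sequence in many copies was therefore under-represented in these lists. Rotated positions were not limited to sequence where peaks can be called, which also limits the comparison of intergenic, intron and exon shares. The comparison of repeat-masked bases therefore does not decide whether H3K9me3 lies over repeats.

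Of the gene groups fixed in advance, 6 carried more peaks than rotated positions, and 1 carried fewer. The groups above were the clustered protocadherins, imprinted genes, C2H2 zinc finger genes, type 1 and type 2 vomeronasal receptors and germline genes, and the group below was the ribosomal protein genes. Protein-coding genes as a whole were overlapped less often than rotated positions: 3539 of 21755 (16.3%) against a median of 19.12% (rotation permutation p = 0.002, the smallest possible). When 10% of the gene body had to be covered, the direction turned and the call was lost (2.40% against 1.95%, permutation p = 0.0699). In the replicates' own lists 25.2% ± 2.81 of protein-coding genes (SD, n = 2) were overlapped. Of the 3539 genes overlapped by a replicated peak, 3186 were also overlapped in the own lists of both replicates. Unless another test is named, tests of the fixed gene groups were 2-sided with 1000 rotations and were adjusted over the 24 lists. Zinc finger, receptor, cytochrome, serpin, defensin and protocadherin genes belong to families with similar copies, and values of single members are uncertain for that reason.

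**Figure D3:**
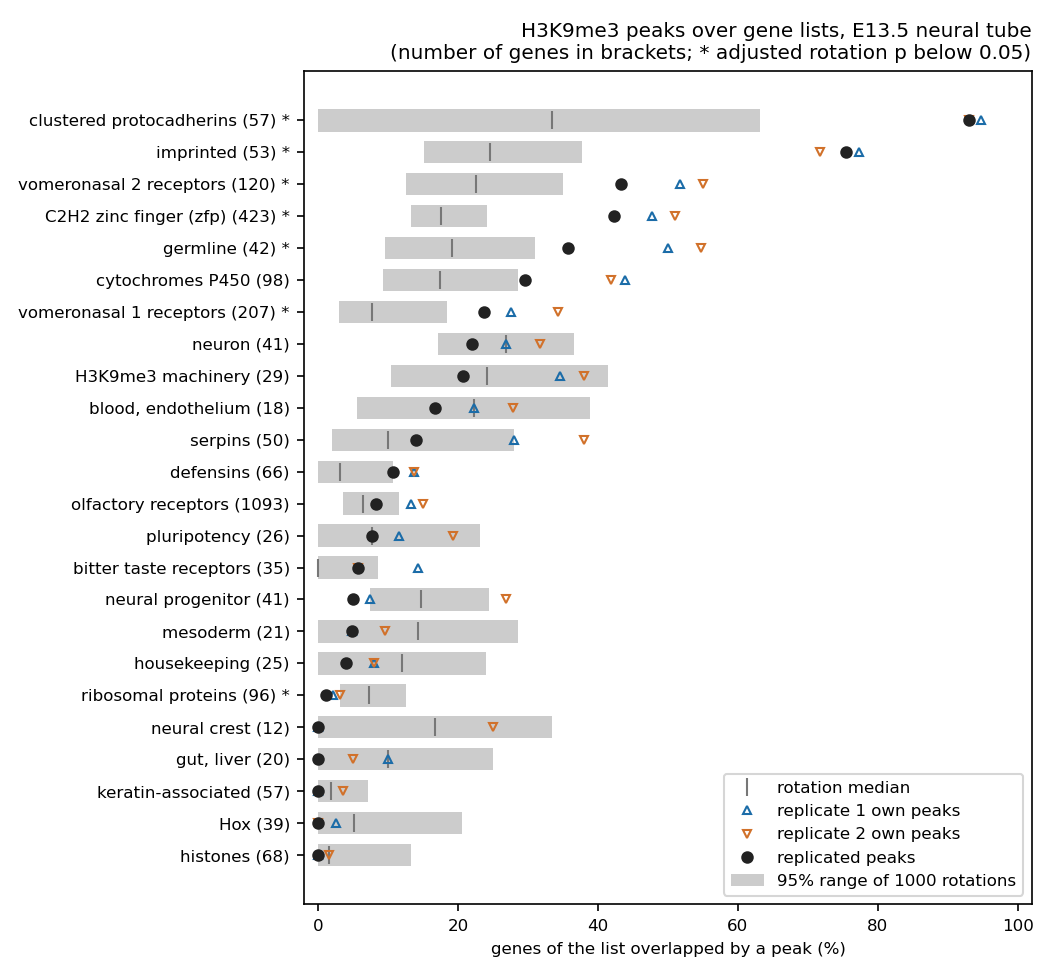
Each row is a fixed gene list with its number of genes, and the horizontal axis gives the percent of its genes overlapped by a peak. Filled circles are replicated peaks, open triangles each replicate's own peaks, and grey bars the 95% range of 1000 rotations of the replicated peaks, with the median as a tick. Protocadherins (93.0%) and imprinted genes (75.5%) lie furthest right of their rotation range, and ribosomal protein genes (1.04%) lie left of theirs.

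The clustered protocadherins, cell-surface adhesion proteins of which single neurons express different sets, had the largest overlapped share of the fixed groups. Peaks overlapped 53 of 57 (93.0%, against a rotation median of 33.3%; adjusted permutation p = 0.024), and 93.9% ± 1.24 in the replicates' own lists (SD, n = 2). In the alpha group 13 of 14 genes were overlapped, in the beta group 22 of 22 and in the gamma group 18 of 21. The 4 members without a peak, named because they were few, were Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5, which lie at the 3′ ends of the alpha and gamma groups. The cluster ran from 36930184 to 37841873 on chromosome 18 and held 355 replicated peaks that covered 338 kb, or 37.1% of it and 43.8% of all covered sequence of that chromosome. Pcdhga1 (37661793 to 37841873) had 102 kb covered, Pcdhga2 97.53 kb, Pcdhga3 92.4 kb, Pcdhgb1 87.1 kb, Pcdhga4 82.9 kb and Pcdhgb2 78.4 kb. These gamma genes share their 3′ exons and overlap one another, so their values are not independent. Their strongest peak had a fold enrichment of 9.42, with 10 and 9.15 in the replicates' own lists. The gene models Gm42416, Gm37013 and Gm37388, which span alpha to gamma, had 323, 312 and 309 kb covered for the same reason. Counted as the 22 beta genes alone, whose bodies do not nest, the group stood at 100% against a rotation median of 0 (adjusted permutation p = 0.012).

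**Figure D4:**
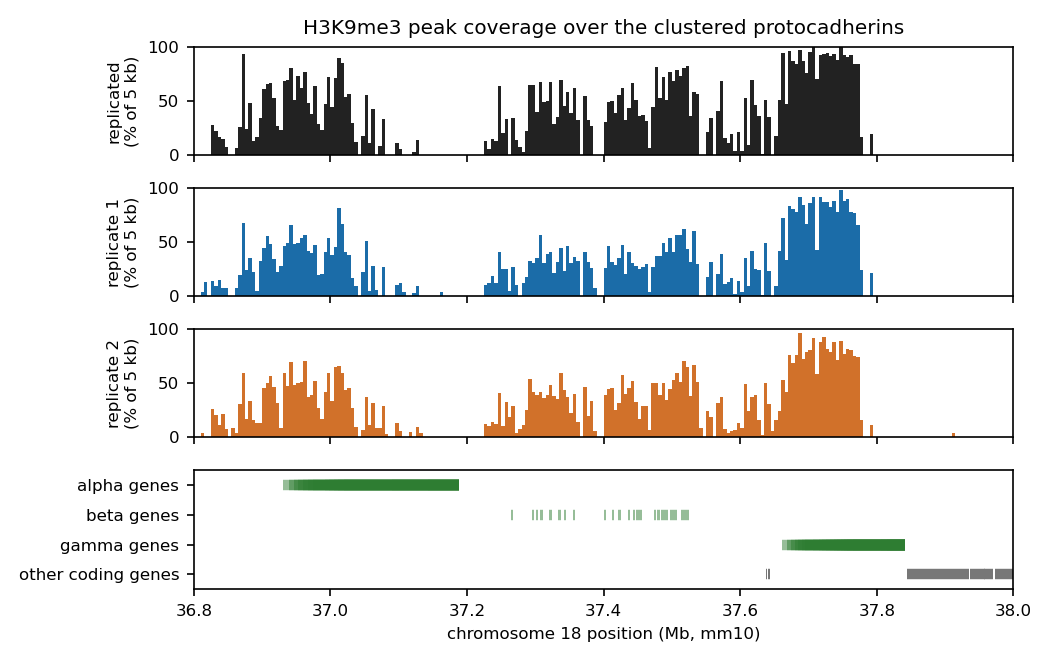
The top 3 tracks give the percent of each 5 kb bin on chromosome 18 covered by replicated, replicate 1 and replicate 2 peaks, and the bottom track the protein-coding gene models, without those named Gm. Coverage in all 3 peak lists starts upstream of the alpha genes (93.3% of the bin from 36870001 for replicated peaks) and is high over the 5′ part of the gamma genes, while the 3′ ends of the alpha and gamma genes, and Diaph1 and Hdac3 to the right, have no replicated peak.

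C2H2 zinc finger genes, which encode DNA-binding proteins, many of them repressors of transposable elements, were covered more often than rotated positions in both replicates. Of 423 genes, 179 (42.3%) were overlapped, against a rotation median of 17.5% (95% range 13.2 to 24.1; adjusted permutation p = 0.016), and 49.4% ± 2.34 in the replicates' own lists (SD, n = 2). The share is that of this list, which was made by gene symbol. In it 388 genes had at least 3 finger motifs, against 644 among all protein-coding genes used. Zfp873 (chromosome 10, 82048123 to 82064745) had a peak of fold enrichment 10.6, with 9.56 and 8.20 in the replicates, and 14.8 kb of its 16623 bp were covered. Zfp110 (chromosome 7, 12834761 to 12850577) reached 10.2, with 7.86 and 9.90 in the replicates, and Zfp90 on chromosome 8 reached 9.03, with 9.62 and 7.03. At the starts of these genes there was no such excess: within 1 kb of the start, 14 of 423 (3.31%) had a peak, against a rotation median of 3.55% (adjusted permutation p = 1).

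The coverage of zinc finger genes lay towards their 3′ ends, where the exon that encodes the finger array is usually found. In the 179 overlapped genes, a mean of 71.8% of the covered bases lay 3′ of the midpoint of the gene, and 142 genes had more than 50% there. The 2-sided permutation of signs over 79 gene clusters gave p = 1e-05, the smallest that 100000 permutations can give. The replicates' own lists gave 71.3% ± 0.10 (SD, n = 2). In 3296 other overlapped genes with several exons the mean was 49.0%. Among 141 zinc finger genes with a covered exon, 49.1% of last-exon bases and 22.4% of other exonic bases were covered, and the last exon was the more covered in 124 of them. In 893 other genes these shares were 15.5% and 13.3%. Along all 422 multi-exon zinc finger genes, coverage was lowest around the start and reached 9.94% in a bin near the end of the gene.

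**Figure D5:**
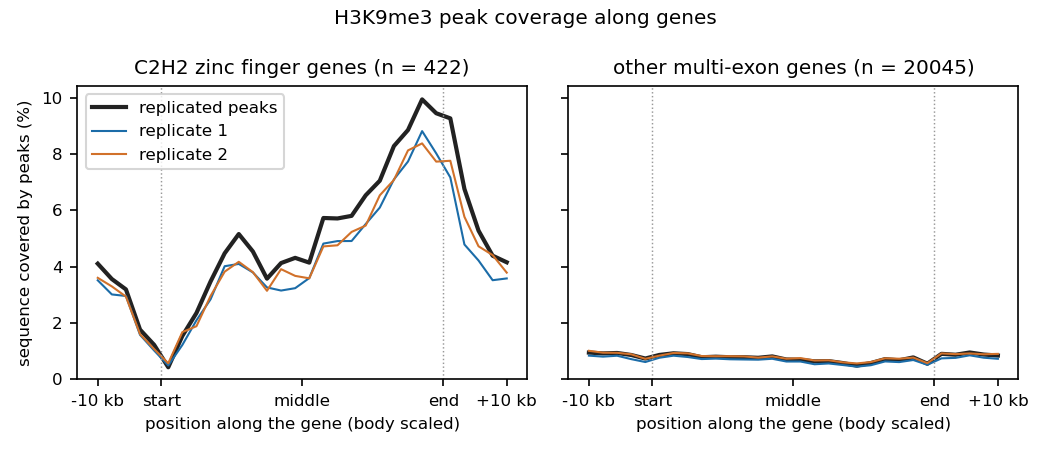
The vertical axis gives the percent of sequence covered by peaks from 10 kb before to 10 kb after the gene, with the gene body scaled to 20 bins, for 422 zinc finger genes (left) and 20045 other genes with several exons (right). In zinc finger genes all 3 peak lists climb from the start to the end of the gene, up to 9.94% for replicated peaks, while the other genes stay below 1.01% throughout.

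Imprinted genes, which are expressed from 1 parental copy, were, after the protocadherins, the group with the largest overlapped share. Peaks overlapped 40 of 53 (75.5%, against a rotation median of 24.5%; adjusted permutation p = 0.016), and 74.5% ± 4.00 in the replicates' own lists (SD, n = 2). Within 1 kb of the annotated start, 21 of 53 (39.6%) had a peak, against a rotation median of 3.77% (adjusted permutation p = 0.012), among them Peg3, Peg10, Snurf, Kcnq1ot1, Meg3 and Nespas. Blcap (chromosome 2, 157556362 to 157571274) and Nnat, which lies within it, shared a peak of fold enrichment 7.14, with 7.50 and 6.03 in the replicates for Blcap and 5.0 and 4.74 for Nnat. Gnas on the same chromosome, the gene of the stimulatory G protein alpha subunit, reached 6.87, with 6.79 and 6.31. Overlapping members were counted separately. Counted once, 31 of 44 remained (70.5%; adjusted permutation p = 0.016). Klf14 (chromosome 6, 30956023 to 30959078), a single-exon transcription factor gene outside the fixed lists, was covered over its whole 3.06 kb with a fold enrichment of 10.3.

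Germline genes, active in germ cells and silent in somatic tissue, carried peaks near their starts. Peaks overlapped 15 of 42 (35.7%, against a rotation median of 19%; adjusted permutation p = 0.034), and 52.4% ± 3.37 in the replicates' own lists (SD, n = 2). Within 1 kb of the start, 10 of 42 (23.8%) had a peak, against a rotation median of 2.38% (adjusted permutation p = 0.012); they were Boll, Brdt, Dazl, Ddx4, Fkbp6, Mael, Stk31, Sycp1, Taf7l and Tex11. By fold enrichment the leading members were Dazl, an RNA-binding protein of germ cells, at 6.58 (replicates 3.68 and 6.63), the helicase gene Ddx4 at 5.18 (5.36 and 4.10) and the meiotic gene Hormad2 at 4.78 (4.65 and 3.79). The peaks were narrow against the genes: 0.531 kb of Dazl and 0.932 kb of Ddx4 were covered, and no member reached 10% of its length. Over whole gene bodies the group missed the threshold with the peaks of replicate 2 alone (54.8% against 38.1%, adjusted permutation p = 0.096) and with 5 kb added on each side (38.1% against 23.8%, adjusted permutation p = 0.155).

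Vomeronasal receptor genes, which encode pheromone receptors, were overlapped more often than rotated positions in both families. Of the type 2 receptors 52 of 120 were overlapped (43.3%, against 22.5%; adjusted permutation p = 0.016; replicates 53.3% ± 2.36, SD, n = 2), and of the type 1 receptors 49 of 207 (23.7%, against 7.73%; adjusted permutation p = 0.029; replicates 30.9% ± 4.78). Vmn2r60 on chromosome 7 had 20.8 kb covered and a fold enrichment of 6.18, Vmn2r16 on chromosome 5 reached 5.98 and Vmn2r107 on chromosome 17 reached 5.58. Among type 1 receptors Vmn1r59, Vmn1r66 and Vmn1r71, all on chromosome 7, reached 5.38, 5.30 and 5.10. Type 2 receptors missed the threshold with the peaks of replicate 2 alone (55% against 39.2%, adjusted permutation p = 0.096) and when 10% of the gene body had to be covered (15.8% against 3.33%, adjusted permutation p = 0.153), and type 1 receptors when 5 kb on each side of the gene were counted (adjusted permutation p = 0.078). Within 1 kb of the start both missed it, at 13.3% against 4.17% for type 2 (adjusted permutation p = 0.067) and 12.6% against 3.38% for type 1 (adjusted permutation p = 0.288). The much larger olfactory receptor family gave 90 of 1093 (8.23%, against 6.40%; adjusted permutation p = 0.570), with Olfr77 on chromosome 9 at a fold enrichment of 5.38. Random lists matched on gene length gave 4.57% (adjusted permutation p = 0.000686), but they do not keep the clustering of these genes, as rotation does. The bitter taste receptors gave 2 of 35 (5.71%, against 0; adjusted permutation p = 0.4), including Tas2r107 at 2.89.

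Ribosomal protein genes, most of which are expressed in every cell, were nearly free of peaks. The list also holds Rpl10l, which is on the germline list too. Peaks overlapped 1 of 96 (1.04%, against a rotation median of 7.29%; adjusted permutation p = 0.032), and 2.60% ± 0.74 in the replicates' own lists (SD, n = 2). The 1 member, named because it was alone, was Rpl3, with a fold enrichment of 2.73 and a peak in the own list of replicate 1 only (3.93). The call was lost when 10% of the gene body had to be covered (adjusted permutation p = 0.378) and within 1 kb of the start (adjusted permutation p = 0.390), with 0 of 96 genes against a rotation median of 3.125% in each. Housekeeping genes gave 1 of 25 (4.00%, against 12%; adjusted permutation p = 0.570), with Tbp at 2.90. No member of the histone (68 genes), Hox (39) or keratin-associated (57) lists was overlapped, against rotation medians of 1.47%, 5.13% and 1.75%. None of these 3 passed the test (adjusted permutation p = 0.836, 0.570 and 0.976), and their rotation ranges included 0.

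Among genes that mark cell types, none of the groups passed the test. Neural progenitor and patterning genes, active in this tissue, were overlapped in 2 of 41 (4.88%, against 14.6%; adjusted permutation p = 0.128), namely Lmx1a, a roof plate factor, at a fold enrichment of 4.38, and Wnt3a, a signalling gene, at 3.39, which had a peak in the own list of replicate 2 only (4.08). The replicates differed widely here, with 7.32% in replicate 1 against a rotation median of 21.95% (adjusted permutation p = 0.027), and 26.8% in replicate 2 against 24.4% (adjusted permutation p = 0.907). Neuronal genes gave 9 of 41 (22%, against 26.8%; adjusted permutation p = 0.570), led by Syt1, a calcium sensor of synaptic vesicles, at 4.92, Nrxn1 at 4.78 and Ntrk3 at 4.76. Markers of mesoderm gave 1 of 21 (4.76%), of blood and endothelium 3 of 18 (16.7%; Tek at 4.32 and Flt1 at 4.21), of neural crest 0 of 12 and of gut and liver 0 of 20, with adjusted permutation p of 0.570, 0.836, 0.402 and 0.357. The replicates' own lists differed for neural crest too, with 0 in replicate 1 against a rotation median of 16.7% (adjusted permutation p = 0.0575). Replicate 2 gave 25% against 25%. Pluripotency genes gave 2 of 26 (7.69%, against 7.69%; adjusted permutation p = 1), namely Zfp42 at 3.53 and Esrrb at 3.29. Genes of the H3K9 methylation machinery gave 6 of 29 (20.7%, against 24.1%; adjusted permutation p = 0.867), led by Smchd1 at 6.18, the Setdb1 partner Atf7ip at 4.71 and the methyltransferase gene Setdb1 at 3.99. Cytochrome P450 genes gave 29 of 98 (29.6%, against 17.3%; adjusted permutation p = 0.128), with Cyp3a16 at 5.38, Cyp2b9 at 5.30 and Cyp2c29 at 5.18. Within 1 kb of their starts, 14.3% of the cytochrome genes had a peak, against 3.06% (adjusted permutation p = 0.012). The call on this group depended on the setting: it also passed with the peaks of replicate 1 alone (43.9% against 26.5%, adjusted permutation p = 0.016), with 5 kb added on each side (40.8% against 22.4%, adjusted permutation p = 0.040), by Fisher's exact test and against length-matched lists. Defensins gave 7 of 66 (10.6%, against 3.03%; adjusted permutation p = 0.144), with Defb33 at 4.98 and Defb48 at 4.71, and serpins 7 of 50 (14%, against 10%; adjusted permutation p = 0.836), with Serpinb9e at 4.78, Serpinb6d at 4.12 and Serpinb9b at 3.99.

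Of the 5 peaks of highest fold enrichment, 3 lay on unplaced or unlocalised contigs, at 12, 11.9 and 11.7. The next, at 11.4, lay on chromosome 12 from 17903498 to 17904192, in exons of the pseudogenes Gm49329 and Gm49331, and was 89.1% repeat-masked. The last, at 10.6, lay on chromosome 10 from 82062875 to 82066587 and covered exonic sequence of Zfp873. The widest peak spanned 11.6 kb on chromosome 7 from 24098384 to 24109977 over Zfp180, with a fold enrichment of 8.14 and 8.37 and 9.96 in the replicates. Mroh2a on chromosome 1 carried 2 of the 5 widest, of 11 and 9.91 kb (88225425 to 88236445 and 88241919 to 88251830), at fold enrichments of 4.50 and 4.12. Zfp110 carried another, of 10.4 kb (12839793 to 12850174). The last, of 8.36 kb, lay between genes on chromosome 4 from 3061662 to 3070021. Apart from these peaks, Skint5 on chromosome 4, of a family that shapes skin T cells, had 75.0 kb of its gene body covered by 140 peaks.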

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

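Peaks outside chromosomes 1 to 19 and X entered no comparison and no test, and 2 sets of them held more peaks than the 3 that a count of 0 allows. On 22 unplaced or unlocalised contigs lay 253 replicated peaks, or 0.828% of the list, with 362 and 360 in the own lists of replicates 1 and 2. Their median fold enrichment was 4.34, against 3.69 on chromosomes 1 to 19 and X, their median width was 632 bp and they covered 270 kb. They made up 9 of the 100 replicated peaks of highest fold enrichment. Chromosome Y held 17 replicated peaks, which covered 9.84 kb at a median fold enrichment of 4.62, and 20 peaks in each replicate's own list.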

How the results depend on the processing

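Choosing the lists without Def6 and Def8, the beta protocadherins alone and the imprinted genes counted once came after the data were seen; these 3 kept direction and side of the threshold. So did replicate overlap (10 alternative values) and the 3′ position in zinc finger genes (4). Genomic features with repeat-masked sequence did so in 21 of 24. The other 3 were promoters, which passed in none of them and lay below their rotation median without replicate 1 (2.35%), without replicate 2 (2.56%) and at 2 kb (5.17%), against a main value above it (2.81%). The zinc finger list kept its call in 7 of 8 alternatives and reversed at transcription starts (3.31% against a rotation median of 3.55%), since its coverage lay away from the starts.

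Chromosome 7 moved from 2.88 to 2.91 times all chromosomes at a −log10 q of at least 2, and stood at 2.45 to 2.48 without either replicate. The rank correlation moved from 0.175 to 0.217 at that threshold, 0.256 with a reciprocal overlap of 50% and 0.224 by −log10 p. The percent of pooled peaks kept moved from 28.3% to 46.7% at that threshold, 29.8% after merging within 1 kb and 11.3% (12238 peaks) with the intersection of the replicates' lists at 50%. The number of lists above rotation, 6, ranged from 4 to 8. The number below, 1, became 1 to 2 without either replicate, 0 when 10% of the gene body or the start had to be covered, and 5 by Fisher's exact test.

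Single lists other than the zinc finger list kept direction and side of the threshold in 158 of 187 alternative values, lost their call in 10, gained one in 10 and changed direction in 9. Without replicate 1, neural progenitor genes (26.8%) and keratin-associated genes (3.51%) lay above rotation, and neither passed. Without replicate 2 they stood at 7.32% and 0, below it. Fisher's test compares with genes of all lengths, and neither it nor the length-matched lists keep the clustering of genes. By Fisher's test, olfactory receptors (8.23% against 16.7%) lay below and passed, whereas they lay above length-matched lists (4.57%) and passed there too. Bitter taste receptors (5.71%), defensins (10.6%) and serpins (14%) lay below, and neuronal (21.95%), blood and endothelial (16.7%) and H3K9 machinery genes (20.7%) above, and none of these 6 passed. For the other values that moved or changed direction, the cause was not tested. Depth being unknown, peaks found in 1 replicate alone were not shown to be absent from the other.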

Other observations

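The tests of gene types and symbol families, of finger number, of GC content, of nested gene models and of weak peaks were chosen after the results were seen. Outside protein-coding genes, immunoglobulin heavy chain variable segments stood out. Peaks overlapped 34 of 218 immunoglobulin V genes (15.6%, against a rotation median of 0.917%; permutation p = 0.001, adjusted p = 0.00367 over 22 gene types) and 40 of 158 V pseudogenes (25.3%, against 0.633%; permutation p = 0.0002, the smallest possible; adjusted p = 0.0011). The replicates' own lists gave 15.6% ± 1.30 and 24.7% ± 2.69 (SD, n = 2). All 34 covered V genes were among the 113 of the heavy chain locus on chromosome 12, and none among the 102 on chromosome 6, which holds the kappa light chain locus. Of the V pseudogenes, 38 of 81 on chromosome 12 and 2 of 74 on chromosome 6 were overlapped. The difference between the loci was not tested. The V genes of T cell receptors gave 2 of 144 (1.39%, against 0.694%; permutation p = 0.644). Unprocessed pseudogenes were overlapped in 210 of 1953 (10.8%, against 4.51%; adjusted permutation p = 0.0011) and processed pseudogenes in 292 of 9849 (2.96%, against 1.503%; adjusted permutation p = 0.0011).

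Of 366 gene families grouped by symbol stem with at least 8 members, 1 lay above rotation after adjustment, the Zfp genes themselves, and 1 below, the solute carrier genes. Solute carriers were overlapped in 51 of 371 (13.7%, against 22.1%; adjusted permutation p = 0.037). At an unadjusted p under 0.05, 7 families lay above and 17 below. The former included the maternal-effect and inflammasome family Nlrp, with 11 of 17 overlapped (64.7%, against 29.4%; permutation p = 0.014, adjusted p = 0.479), the secretoglobins, with 11 of 34 (32.4%, against 2.94%; adjusted permutation p = 0.562), and the natural killer receptors Klra, with 7 of 11 (63.6%, against 9.09%; adjusted permutation p = 0.593). Chosen after its value was seen, Nlrp5 on chromosome 7 had 24.7 kb covered by 33 peaks. Skint genes gave 9 of 11 (81.8%, against 36.4%; permutation p = 0.056).

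Peaks over the 3′ ends of zinc finger genes could in part come from reads shared between similar copies. In genes whose last exon was at least 90% unique 31-mers, 76.5% of covered bases still lay 3′ of the midpoint (95% interval 69.0 to 83.2, 106 genes). This argues against shared reads as the whole cause of the 3′ position. Genes with a less unique last exon were overlapped more often, 73 of 141 (51.8%) against 106 of 280 (37.9%). Shared reads therefore stay open as a part of the overlap itself, which the 3′ share does not test. Zinc finger last exons were 21.8 times as covered as last exons of other genes matched on GC content and length (interval 17.3 to 26.7), which argues against GC content as the whole cause. Genes with at least 3 fingers and a KRAB box were overlapped more often than those without, by 25.5 percentage points (interval 10.5 to 41.5; 136 of 262 against 101 of 382), consistent with the hypothesis that the pattern belongs more to KRAB genes than to all C2H2 genes. At like numbers of fingers the difference was 26.1 points (interval 10.7 to 44.7) with 3 to 8 fingers, 21.04 (2.21 to 41.3) with 9 to 14 and −12.8 (−30.4 to 9.02) with 15 or more, so a difference was seen up to 14 fingers and was not detectable above.

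For the clustered protocadherins, shared reads and nested gene models were the candidate technical explanations. In the peaks of the cluster 91.7% of 31-mers occurred once in the genome, and 100% of the beta genes, which do not nest, were overlapped. The first value was near that of all replicated peaks (89.7%), which hold little many-copy sequence. It shows that most sequence in these peaks was single-copy at 31 bp. Being measured inside called peaks, it does not decide on shared reads. The second value argues against nested gene models as the whole cause. No biological explanation of this pattern was tested, as the design has a single group.

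Weak peaks were found in 1 replicate only more often than strong ones, with a shared percent in the strongest 10% at least 2.76 times that of the weakest 10% in both replicates. That ratio restates the shares by strength and does not test whether unshared peaks lie near the calling threshold. With only peaks of a −log10 q of at least 2 in both lists, sharing was 29.5% in replicate 1, lower than among all peaks, and 37.4% in replicate 2, higher than among all, but that threshold also shortens the list to be matched and decides nothing, so weak calls stay open as an explanation. Unshared peaks were no richer in repeated sequence: the percent of 31-mers found once in shared minus unshared peaks was −0.161 points in replicate 1 and −0.270 in replicate 2. This argues against many-copy sequence inside the called peaks as what set unshared peaks apart. Both lists held little of it, with 3.35% and 3.48% of 31-mers present 10 times or more. Many-copy sequence where no peak was called is not covered by these values. Differences in depth, in the control files or in the biology of the replicates stay open, as none was tested.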
